A study of Homo sapiens with 16 samples.

How the data were processed

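The series holds RNA sequencing of 2 human melanoma cell lines, A875 and HMVII, per the labels. Each line was treated with the vehicle DMSO, with GSK126, with di-ABZI, or with both compounds, and each of these 8 groups has 2 libraries, 16 in all. The labels give no dose, no treatment time and no statement that the 2 libraries of a group came from separate cultures. Per the labels' protocols, RNA was extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit for Illumina, and nothing in them states that strand was kept. The comparisons below therefore rest on 2 libraries per group, and their p-values measure only the spread between libraries, which may be technical. If each group is a single culture, a difference between groups can reflect the cultures as well as the compound.

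The authors deposited 1 table of FPKM values (fragments scaled to the exon length of the gene and to the total counted in the library), per the file headers, with 1 column for each library and 37370 genes given by Ensembl ID, symbol and position. The aligner, the counting tool and the filters are not given in the sources used here. The submitters' processing notes list only the mouse build mm9, while all 37370 IDs are human genes of GENCODE release 29 and 37334 of them carry its GRCh38 position, so positions are given as the deposited table has them. In the 8 libraries numbered 2 the deposited FPKM column holds no value for 2808 genes, none of which lack a value in the libraries numbered 1. For this reason those columns are recorded under another unit, although their other values are on the same FPKM scale. The 2808 genes were not tested, and 2 of them reached 1 FPKM in 2 libraries. The table gives some symbols as dates, as a spreadsheet program writes them, and such genes were not named. No other sample or column was left out.

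Fragment counts were recovered from the FPKM values by multiplying each value by the gene's exon length in GENCODE release 29 and dividing by a scale for the library. That scale was the most common ratio of the library's low values to those of A875 DMSO replicate 1. In A875 DMSO replicate 1 the most common low product was read as 1 fragment. Over values of up to 200 fragments, 100% were whole within 0.02 in the 16 libraries. The totals recovered in this way lay between 25663007 and 30098308 fragments per library. A count of 0 in a library allows a level of up to 3 fragments, a floor that covers counting error only.

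For each gene, log2(FPKM + 1) was fitted with a mean for each of the 8 groups over all 16 libraries, using lmFit and eBayes with a mean-variance trend in limma 3.58.1 under R 4.3.3. A gene was tested if it reached 1 FPKM in at least 2 of the 16 libraries and had a value in each, which left 15535 genes. The fit had 8 residual degrees of freedom and 2.41 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low levels, and are given with the standard error (SE) of the fit. Levels are given as the mean FPKM with the standard deviation (SD) over the 2 libraries of a group.

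The comparisons were each treatment against DMSO in each line, the combination against each compound alone, the departure from additivity in each line (the combination minus GSK126, less diABZI minus DMSO, on the log2 scale), and the difference between the lines in each treatment's change (HMVII minus A875). Genes called in both lines were counted beside the number that independent lists would share, with a one-sided Fisher's exact test, which describes the overlap only because genes are not independent replicates. Of 36 gene lists fixed before the data were examined, the 34 with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of each comparison, with camera at an estimated correlation, and with fry. The members past the threshold were counted with the adjustment over all genes and adjusted over the list alone.

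Before the data were examined, the rule for the genes named was also fixed. It took, in each comparison with DMSO, the 7 genes with the largest rise and the 7 with the largest fall among called genes with a symbol, at least 1 FPKM in the higher group and no overlap between the libraries of the 2 groups. It took the 3 largest in each direction for the other comparisons within a line, up to 4 called members of each list, and a fixed set of polycomb, STING pathway, interferon, antigen presentation, stress and melanocyte genes. Pseudogenes, very short RNAs and genes inside or antisense to others share reads with their neighbours or copies, and their values are uncertain. Some genes that the rule names are not reported here.

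Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, leaving out each library in turn, a separate fit for each line, and a minimum change of 2-fold. Voom of limma on the recovered counts was added after the data were seen. The fit was tested on simulated counts with 200 genes changed in 1 group. The counts were drawn around the DMSO means of each line with 1.5 times the counting variance and no spread between cultures. Far more genes were called in the data than were changed there, so the shares below do not carry over to the real comparisons. For GSK126 against DMSO in A875 (15140 genes), 58% of genes changed 1.2-fold, 74% changed 1.5-fold and 94% changed 2-fold or 4-fold were recovered, and unchanged genes made up 12.1% of the calls. For the same comparison in HMVII (15125 genes), 46%, 84%, 92% and 96% were recovered at 1.2-fold, 1.5-fold, 2-fold and 4-fold, and unchanged genes made up 14.5% of the calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.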

Results

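RNA levels were measured in 2 human melanoma lines. A875 and HMVII are established lines grown from melanomas. GSK126 inhibits EZH2, the enzyme of polycomb repressive complex 2 (PRC2), which places the silencing mark H3K27me3. diABZI (di-ABZI in the labels) is a small molecule that activates STING, the adaptor through which cytosolic DNA induces interferon. Each line had 2 libraries with DMSO, 2 with GSK126, 2 with diABZI and 2 with both compounds. The recovered totals were 26016412 to 29918689 fragments per library in A875 and 25663007 to 30098308 in HMVII. Between 11700 and 12658 genes reached 1 FPKM in the A875 libraries, and between 12882 and 13143 did so in the HMVII libraries. Mitochondrially encoded genes took between 1.942% and 4.075% of the fragments in A875 and between 7.875% and 8.223% in HMVII.

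EZH2 itself (ENSG00000106462, chromosome 7, 148807383 to 148884321) stood at 25.7 ± 0.18 FPKM (SD, n = 2) in A875 with DMSO and at 5.76 ± 0.024 in HMVII with DMSO. TMEM173, the gene of STING (ENSG00000184584, chromosome 5, 139475534 to 139482935), stood at 7.19 ± 0.0092 FPKM in A875 and 7.05 ± 0.58 in HMVII. CGAS, which senses cytosolic DNA upstream of STING (ENSG00000164430), had a mean of at most 0.012 FPKM in any of the 8 groups and was not tested. IFNB1, the interferon beta gene (ENSG00000171855), was below the filter as well, with 0.446 ± 0.38 FPKM in HMVII with diABZI and 0.608 ± 0.23 with the combination, beside 0.0214 ± 0.03 with DMSO. In A875 the mean of IFNB1 was at most 0.0195 FPKM in the 4 groups.

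**Figure D1:**
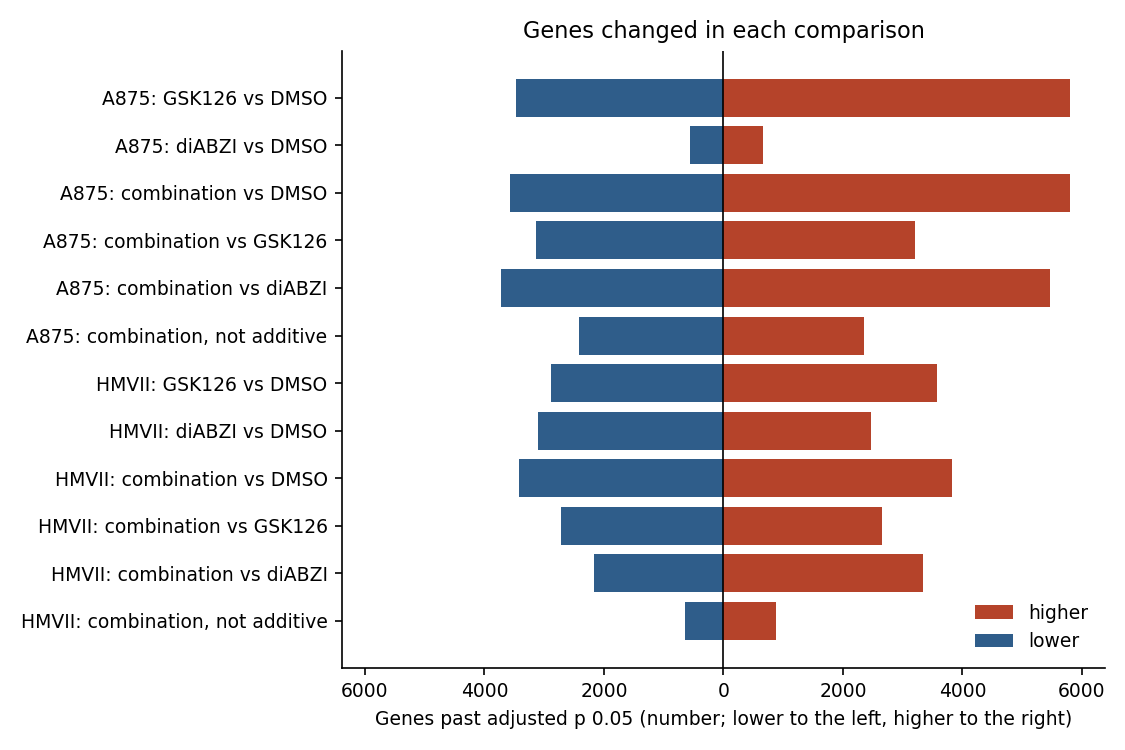
Number of genes past a limma adjusted p of 0.05 in each comparison within a line (bars), lower to the left and higher to the right. diABZI against DMSO in A875 gave 1217 genes, and in HMVII 5579.

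The first question was what changed with GSK126 in A875, where EZH2 activity and H3K27me3 were not measured. With GSK126, genes of glycolysis and the hypoxia response rose together. ANGPTL4, a lipoprotein lipase inhibitor (ENSG00000167772, chromosome 19, 8363289 to 8374373), went from 1.31 ± 0.015 to 51.2 ± 0.42 FPKM, a log2 change of 4.50 ± 0.07 (SE). SLC2A3, a glucose transporter, rose by 3.51 ± 0.03 and NDRG1 by 2.64 ± 0.02. NGFR, the low-affinity nerve growth factor receptor of neural crest cells (ENSG00000064300, chromosome 17, 49495293 to 49515017), fell from 643 ± 5.6 to 86.0 ± 0.84 FPKM (log2 change of -2.89 ± 0.05). Among the large changes were also rises of AOC1 (4.42 ± 0.04), IGFBP2 (3.52 ± 0.05), PAEP (3.12 ± 0.06), SPP1, which encodes osteopontin (2.85 ± 0.02), and SPOCK1 (2.85 ± 0.03). The other large falls were those of PDE1C (-1.82 ± 0.04), THBS1 (-1.80 ± 0.04), TAGLN (-1.78 ± 0.07), SYTL3 (-1.78 ± 0.07) and KRT14 (-1.67 ± 0.09). Adjusted p of these genes lay between 4.64e-14 for SPP1 and 4.16e-08 for KRT14.

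Of 36 tested genes of glycolysis and hypoxia, 34 rose and 0 fell in A875 with GSK126 (34 and 0 adjusted over the list alone, camera adjusted p = 4.55e-15). Of 45 tested developmental regulators known as PRC2 targets, 26 rose, 5 fell and 14 did not pass (26 and 5 adjusted over the list alone). BMP7, a growth factor gene, rose by 1.55 ± 0.06, FOXA2 by 1.44 ± 0.08, and SOX2 from 0.0207 ± 0.029 to 1.62 ± 0.15 FPKM. This list passed camera with adjusted p = 0.0247, but not with adjusted p = 0.117 with an estimated correlation. Genes known to be silenced by EZH2 in tumours did not pass as a list, with 13 of 30 up and 10 down (camera adjusted p = 0.829). Of 61 tested interferon-stimulated genes, 44 rose and 8 fell (45 and 8 adjusted over the list alone, camera adjusted p = 2.62e-05). IFI6 rose by 2.79 ± 0.05, IFITM1 by 1.98 ± 0.11 and IFIT1 by 1.23 ± 0.05. In the list for MHC class I antigen presentation 15 of 21 genes rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 0.00328). HLA-B went from 8.30 ± 0.33 to 44.0 ± 0.46 FPKM, and B2M, the light chain of MHC class I, rose by 0.65 ± 0.02. CD274, which encodes the checkpoint ligand PD-L1, fell from 2.84 ± 0.048 to 0.834 ± 0.018 FPKM.

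Cell cycle genes went down in A875 with GSK126. Of 48 tested genes of G2/M and mitosis 36 fell and 2 rose (36 and 2 adjusted over the list alone, camera adjusted p = 9.57e-11), among them NCAPG (-0.81 ± 0.04) and FOXM1 (-0.63 ± 0.03). Of 49 genes of G1/S and DNA replication 29 fell and 4 rose (31 and 4 adjusted over the list alone, camera adjusted p = 1.12e-06). Of 37 genes of the invasive, AXL-type melanoma state 23 fell and 12 rose (23 and 12 adjusted over the list alone, camera adjusted p = 5.36e-05), with MMP1, a collagenase, up by 2.26 ± 0.08 and CYR61 down (-1.67 ± 0.04). Of 27 senescence-associated secreted factors 21 rose and 3 fell (21 and 3 adjusted over the list alone, camera adjusted p = 0.000578). ANGPTL4 and IGFBP2 are among them. Of 13 mitochondrially encoded genes 12 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.47e-07), and MT-CO2 rose by 1.38 ± 0.02, or 0.26 after quantile normalization. EZH2 (0.08 ± 0.04, adjusted p = 0.0841), SUZ12 (-0.07 ± 0.03, adjusted p = 0.0512) and TBK1 (-0.04 ± 0.05, adjusted p = 0.496) did not pass, and TMEM173 rose by 0.50 ± 0.04 (adjusted p = 2.46e-06). The melanocyte regulator MITF fell (-0.51 ± 0.02).

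In all, 9261 of 15535 genes passed in A875 with GSK126, 5794 higher and 3467 lower, and 472 rose and 100 fell by at least 2-fold. After quantile normalization 3969 were higher and 4770 lower, 302 and 138 of them by at least 2-fold, and the median change over all genes moved from 0.071 to -0.026. With a pseudocount of 0.1 the genes changed by at least 2-fold were 1450 up and 212 down. Lists with adjusted p under 0.05 by camera at the preset correlation that went over it with an estimated correlation were also the anti-apoptotic genes (1 rose and 6 of 10 fell, adjusted p = 0.0542 with an estimated correlation) and the genes of the ATF4 stress response (11 rose and 18 of 33 fell, adjusted p = 0.0624 with an estimated correlation).

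The next question was how A875 responded to the STING agonist alone. diABZI raised a small set of interferon-induced genes in A875. CCL5, a T cell chemokine (ENSG00000271503, chromosome 17, 35871491 to 35880793), went from 0.395 ± 0.041 to 12.8 ± 0.013 FPKM (3.30 ± 0.05), and ISG15, a ubiquitin-like antiviral protein (ENSG00000187608, chromosome 1, 1001138 to 1014540), from 11.3 ± 0.019 to 80.5 ± 0.30 FPKM (2.73 ± 0.09). OASL rose by 1.66 ± 0.04, the helicase gene DDX60 by 1.45 ± 0.03, RARRES3 by 1.37 ± 0.11, IFIT3 by 1.37 ± 0.04 and IFIT2 by 1.25 ± 0.06. The falls named by the fixed rule, which asks for no overlap between the libraries, were smaller, with CHCHD10, a mitochondrial protein gene, at -1.10 ± 0.18, the alkaline phosphatase gene ALPP at -0.48 ± 0.04 and LPP at -0.44 ± 0.02. The short RNA BCYRN1 (-0.74 ± 0.18), the intronic ACAP2-IT1 (-0.48 ± 0.13) and the pseudogenes HMGN1P32 (-0.80 ± 0.20) and NDUFB9P2 (-0.45 ± 0.12) also passed, but can share reads with other loci. Without A875 DMSO replicate 1 the change of HMGN1P32 was -0.48.

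Of 61 interferon-stimulated genes, 25 rose, 0 fell and 36 did not pass in A875 with diABZI (34 rose and 1 fell adjusted over the list alone), with a median change of 0.12 (camera adjusted p = 6e-18). B2M rose by 0.56 ± 0.02 and HLA-B by 0.24 ± 0.04, and 3 of 21 MHC class I genes rose in all (4 adjusted over the list alone, camera adjusted p = 7.51e-05). The mitochondrially encoded genes rose again, 13 of 13 (13 adjusted over the list alone, camera adjusted p = 3.57e-26), as the mitochondrial share of fragments went from 1.942% and 1.965% in the DMSO libraries to 2.669% in both diABZI libraries. PMAIP1, the gene of the pro-apoptotic protein NOXA, rose by 0.80 ± 0.03. Of 35 p53 targets 7 fell (8 adjusted over the list alone, camera adjusted p = 1.71e-05), and of 37 invasive AXL-type genes 9 fell and 1 rose (14 and 3 adjusted over the list alone, camera adjusted p = 1.25e-05), each by less than 0.30 on the log2 scale. EZH2 rose slightly (0.17 ± 0.04, adjusted p = 0.0212).

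Past the threshold were 1217 genes in A875 with diABZI, 660 higher and 557 lower, of which 12 rose and 7 fell by at least 2-fold, or 31 and 16 with a pseudocount of 0.1. Quantile normalization gave 374 higher and 507 lower, voom on the recovered counts gave 1867 genes, and leaving out any single library of the 2 groups gave between 581 and 610 genes, of which 523 to 538 were among the 1217.

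The combination asked whether the compounds together did more than each alone. In A875 the interferon response was then far stronger than with either compound. IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218) went from 10.9 ± 0.73 FPKM with DMSO to 903 ± 9.7 (6.25 ± 0.05), and OAS2, an antiviral oligoadenylate synthetase (ENSG00000111335, chromosome 12, 112978395 to 113011723), from 0.272 ± 0.017 to 78.0 ± 0.61 FPKM (5.96 ± 0.04). IFIT1 rose by 5.58 ± 0.05, ISG15 by 5.49 ± 0.09, IFITM1 by 5.41 ± 0.11 and CCL5 by 5.28 ± 0.05, and ANGPTL4 stayed high (4.62 ± 0.07). The chemokine genes CXCL11 (2.79 ± 0.07) and CXCL10 (2.53 ± 0.13) rose too. Large falls resembled those with GSK126, with NGFR at -2.63 ± 0.05, PDE1C at -1.95 ± 0.04, TAGLN at -1.84 ± 0.07 and THBS1 at -1.79 ± 0.04, beside LPP (-1.88 ± 0.02) and C9orf135 (-1.86 ± 0.11). Adjusted p of these genes was 8.12e-08 for C9orf135 and lower for the others.

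In A875 with the combination 60 of 61 interferon-stimulated genes rose and 0 fell (60 and 0 adjusted over the list alone, camera adjusted p = 1.67e-29), 52 of them by at least 2-fold, with a median of 2.10. Of 21 MHC class I genes 19 rose and 1 fell (19 and 2 adjusted over the list alone, camera adjusted p = 8.61e-08). HLA-B reached 115 ± 1.2 FPKM, HLA-C rose by 2.55 ± 0.06, PSMB9, an immunoproteasome subunit, by 2.53 ± 0.05 and B2M by 1.72 ± 0.02. Of 9 chemokine genes 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00571), and of 20 components of the cGAS-STING pathway 12 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.0278, adjusted p = 0.067 with an estimated correlation). IRF7 rose by 3.23 ± 0.09, IFI16 by 2.17 ± 0.03 and TMEM173 by 0.996 ± 0.044. The glycolysis and hypoxia genes rose in 36 of 36 (36 adjusted over the list alone, camera adjusted p = 3.88e-15). PRC2 target regulators rose in 30 of 45 and fell in 2 (30 and 3 adjusted over the list alone, camera adjusted p = 0.00213), and G2/M genes fell in 44 of 48 and rose in 1 (44 and 1 adjusted over the list alone, camera adjusted p = 1.4e-18), with ASPM at -1.01 ± 0.04 and PLK1 at -0.88 ± 0.04. Pro-apoptotic genes rose in 17 of 24 and fell in 4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.0122), with BMF up by 1.73 ± 0.03 and TNFSF10, the gene of TRAIL, by 1.67 ± 0.07. CD274 fell by less than with GSK126 alone (-0.37 ± 0.07).

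Against DMSO, 9367 genes passed in A875 with the combination, 5802 higher and 3565 lower, 605 and 144 of them by at least 2-fold, or 1451 and 313 with a pseudocount of 0.1. Quantile normalization gave 4126 higher and 4997 lower.

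Set against GSK126 alone in A875, the combination raised CCL5 by 5.05 ± 0.05, OAS2 by 4.89 ± 0.04 and ISG15 by 4.67 ± 0.09. All 61 interferon-stimulated genes rose (61 adjusted over the list alone, camera adjusted p = 2.05e-58), as did CD274 (0.69 ± 0.07). SLC26A2, a sulfate transporter gene, fell (-1.33 ± 0.02), as did MT-ND4L (-1.27 ± 0.05) and the ribosomal RNA pseudogene RNA5SP323 (-1.45 ± 0.20), whose reads can come from other copies. The test called 6340 genes, 3207 higher and 3133 lower, 100 and 36 of them by at least 2-fold, or 156 and 154 with a pseudocount of 0.1. Set against diABZI alone in A875, the combination raised OAS2 by 5.50 ± 0.04, IFI6 by 5.41 ± 0.05 and IFITM1 by 5.27 ± 0.11, and 60 of 61 interferon-stimulated genes (60 adjusted over the list alone, camera adjusted p = 5.88e-30). NGFR (-2.45 ± 0.05) and PDE1C (-1.86 ± 0.04) were lower. The test called 9191 genes, 5469 higher and 3722 lower, 593 and 116 of them by at least 2-fold (1427 and 267 with a pseudocount of 0.1), and quantile normalization gave 4026 higher and 5039 lower.

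The departure from additivity was tested on the log2 scale. In A875, 60 of 61 interferon-stimulated genes lay above the sum of the single-compound changes and 0 below it (60 and 0 adjusted over the list alone, camera adjusted p = 1.71e-63), by a median of 1.49. OAS2 exceeded the sum by 4.43 ± 0.05, IFI27 by 3.54 ± 0.10, IFI44 by 3.43 ± 0.11, ISG15 by 1.94 ± 0.13 and CCL5 by 1.75 ± 0.07. On the FPKM scale itself, 61 of 61 lay above the sum in both libraries. This adds little, since a gene raised by both compounds and additive on the log2 scale also exceeds the sum there. MHC class I genes exceeded the sum in 18 of 21 and fell short in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 3.07e-13), led by PSMB9 (2.00 ± 0.07) and TAP1, a peptide transporter gene (1.45 ± 0.07). Of 17 immune checkpoint genes and ligands 12 exceeded it (14 adjusted over the list alone, camera adjusted p = 6.11e-06). TMEM173 exceeded it by 0.40 ± 0.06 and CD274 by 0.68 ± 0.09. The mitochondrial share of fragments was 4.068% and 4.075% with GSK126, 2.669% with diABZI and 2.239% and 2.246% with the combination. All 13 mitochondrially encoded genes, which follow that share, fell short of the sum (13 adjusted over the list alone, camera adjusted p = 4.71e-20), led by MT-ATP6 at -1.92 ± 0.06. Its nuclear copy MTATP6P1 (-1.97 ± 0.07) shares its reads, and the pseudogene HLA-Z (-2.02 ± 0.67) was -1.26 without A875 GSK126 replicate 1. Of 48 G2/M genes 36 fell below the sum (39 adjusted over the list alone, camera adjusted p = 2.49e-14). In all 4768 genes departed from additivity in A875, 2347 above and 2421 below, 101 and 64 of them by at least 2-fold, or 151 and 191 with a pseudocount of 0.1.

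**Figure D2:**
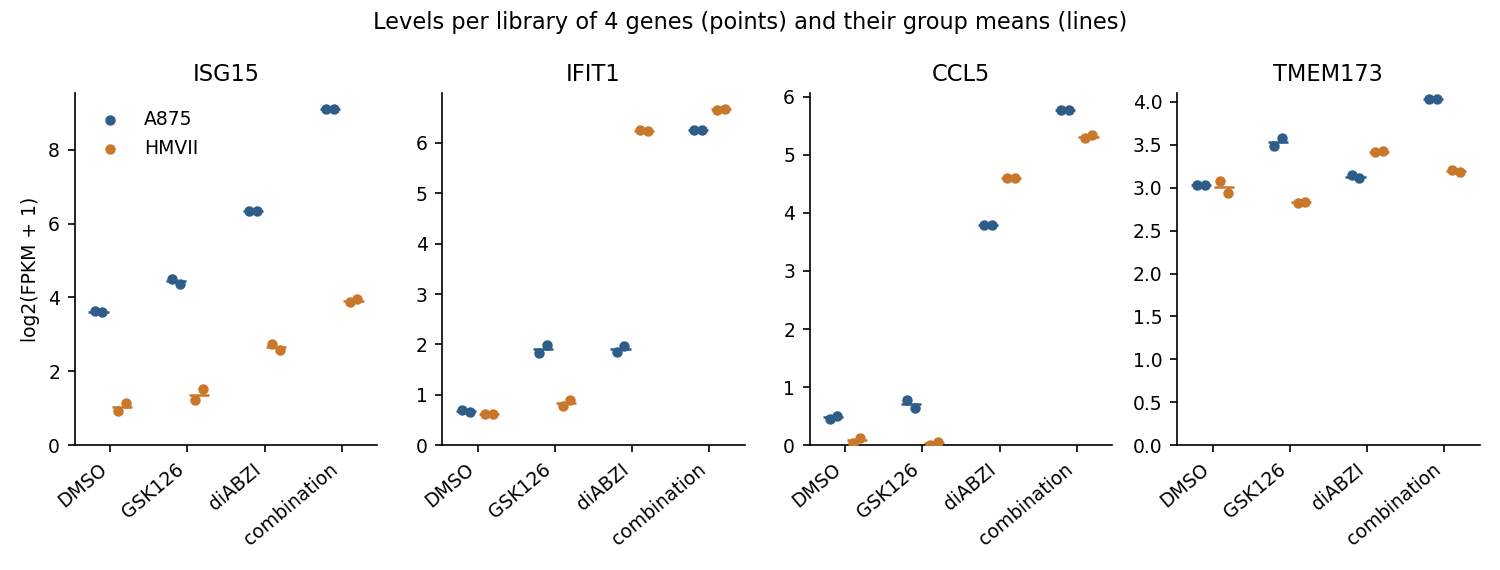
Levels of ISG15, IFIT1, CCL5 and TMEM173 on the log2(FPKM + 1) scale in each library (points, 2 per group) with the group means (lines), for A875 (blue) and HMVII (orange). ISG15 averaged 551 FPKM in A875 with the combination, beside 20.7 with GSK126 and 80.5 with diABZI.

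In HMVII with GSK126, cell cycle and stress genes changed. KIF20A, a mitotic kinesin (ENSG00000112984, chromosome 5, 138178719 to 138187715), went from 6.63 ± 0.50 to 21.3 ± 0.38 FPKM (1.55 ± 0.04). CENPE rose by 1.39 ± 0.03, CDC20 by 1.37 ± 0.04 and CCNB1, which encodes cyclin B1, by 1.37 ± 0.02. HSPA6, an inducible heat shock gene (ENSG00000173110, chromosome 1, 161524540 to 161526910), went from 19.4 ± 0.18 to 1.49 ± 0.22 FPKM (-3.04 ± 0.09), and the haem oxygenase gene HMOX1 (-1.33 ± 0.03) and HSPA1B (-1.30 ± 0.03) fell as well. CYP1A1, a xenobiotic-metabolising enzyme (1.57 ± 0.08), CST1 (1.56 ± 0.17) and ANKRD1 (1.40 ± 0.04) rose, and PRSS33 (-1.31 ± 0.05) and ITGA10 (-1.13 ± 0.05) fell. The pseudogene SEPT14P4 (-1.17 ± 0.42, adjusted p = 0.0437) and the precursor MIRLET7A2 (-1.08 ± 0.34, adjusted p = 0.0266) are short and their values uncertain.

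All 48 G2/M genes rose in HMVII with GSK126 (48 adjusted over the list alone, camera adjusted p = 2.79e-40), by a median of 0.94, and 45 of 49 genes of G1/S and DNA replication rose while 1 fell (45 and 1 adjusted over the list alone, camera adjusted p = 3.55e-18), with RRM2 up by 0.83 ± 0.02. Endoplasmic reticulum (ER) chaperone genes fell in 22 of 32 and rose in 4 (23 and 5 adjusted over the list alone, camera adjusted p = 4.01e-09). CALR, the gene of calreticulin, went from 277 ± 4.2 to 146 ± 0.28 FPKM, and HSPA5, the gene of BiP, fell from 681 ± 5.9 to 470 ± 4.8 FPKM (-0.54 ± 0.01). Heat shock and oxidative stress genes fell in 14 of 28 and rose in 6 (15 and 6 adjusted over the list alone, camera adjusted p = 0.000485). Oxidative phosphorylation genes rose in 26 of 36 and fell in 1 (28 and 1 adjusted over the list alone, camera adjusted p = 3.24e-08), and cholesterol synthesis genes rose in 20 of 33 and fell in 2 (21 and 2 adjusted over the list alone, camera adjusted p = 7.54e-05). Ribosomal protein genes fell in 51 of 58 and rose in 2 (53 and 2 adjusted over the list alone, camera adjusted p = 5.33e-22, adjusted p = 0.0507 with an estimated correlation).

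The PRC2 target regulators did not pass as a list in HMVII with GSK126, with 6 of 45 up and 5 down (4 and 5 adjusted over the list alone, camera adjusted p = 0.9), nor did the interferon-stimulated genes, with 23 of 61 up and 12 down (23 and 12 adjusted over the list alone, camera adjusted p = 0.288). EZH2 rose by 0.48 ± 0.04, TMEM173 fell by 0.18 on the log2 scale (adjusted p = 0.00687), and CCL5 (-0.05 ± 0.05, adjusted p = 0.457) and CD274 (0.10 ± 0.07, adjusted p = 0.291) did not pass. Without HMVII DMSO replicate 1 the change of TMEM173 was -0.11. Past the threshold were 6458 genes, 3576 higher and 2882 lower, 52 and 29 of them by at least 2-fold, or 150 and 76 with a pseudocount of 0.1.

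diABZI alone induced a strong interferon response in HMVII. IFIT1, which binds viral RNA (ENSG00000185745, chromosome 10, 89392546 to 89406486), went from 0.541 ± 0.011 to 74.5 ± 0.44 FPKM (5.61 ± 0.05), OAS2 from 0.0628 ± 0.027 to 49.2 ± 0.61 FPKM (5.56 ± 0.04) and CCL5 from 0.0615 ± 0.051 to 23.3 ± 0.022 FPKM (4.52 ± 0.05). IFIT3 rose by 5.50 ± 0.04, IFI44 by 5.34 ± 0.08, DDX60 by 4.91 ± 0.03, DDX58, which encodes the RNA sensor RIG-I, by 4.84 ± 0.03 and OASL by 4.80 ± 0.04. Large falls were those of ZMAT3, an RNA-binding p53 target (-1.64 ± 0.03), the ceramide kinase gene CERK (-1.54 ± 0.06), the non-coding RNA DANCR (-1.46 ± 0.07), HTRA1 (-1.29 ± 0.08), ODC1, the first enzyme of polyamine synthesis (-1.24 ± 0.03), TKTL1 (-1.24 ± 0.07) and ZNF595 (-1.23 ± 0.03). Adjusted p of these genes was 7.18e-07 for HTRA1 and lower for the others.

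Of 61 interferon-stimulated genes 59 rose and 0 fell in HMVII with diABZI (60 and 0 adjusted over the list alone, camera adjusted p = 8.48e-72), 53 of them by at least 2-fold, with a median of 2.61. The interferon lambda genes IFNL3 and IFNL1 were listed at 0 with DMSO and averaged 1.39 ± 0.57 and 1.13 ± 0.17 FPKM with diABZI. Of 21 MHC class I genes 20 rose (20 adjusted over the list alone, camera adjusted p = 1.69e-20), TAP1 by 2.01 ± 0.05, and the remaining one, B2M, was listed at 0. ER chaperone genes rose in 26 of 32 and fell in 1 (26 and 1 adjusted over the list alone, camera adjusted p = 5.41e-13), with PDIA4 up by 0.66 ± 0.02 and HSPA5 by 0.42 ± 0.01. Melanocyte differentiation genes fell in 28 of 38 and rose in 1 (29 and 1 adjusted over the list alone, camera adjusted p = 2.53e-08). DCT, a melanin synthesis enzyme gene, went from 89.0 ± 1.2 to 41.7 ± 0.1 FPKM. Cholesterol synthesis genes fell in 20 of 33 (20 down and 1 up adjusted over the list alone, camera adjusted p = 2.03e-06), and ATF4 and CHOP stress response genes fell in 19 of 33 and rose in 3 (19 and 3 adjusted over the list alone, camera adjusted p = 0.00318), although WARS, a tRNA synthetase gene induced by interferon, rose by 2.08 ± 0.02. DDIT3, the gene of CHOP itself, went up, from 88.7 ± 1.2 FPKM with DMSO to 120.9 ± 2.9 with diABZI. The pro-apoptotic genes TNFSF10 (1.76 ± 0.07), XAF1 (1.74 ± 0.06) and PMAIP1 (1.68 ± 0.03) rose, as did CD274 (0.65 ± 0.07) and TMEM173 (0.41 ± 0.04). The test called 5579 genes, 2477 higher and 3102 lower, 142 and 30 of them by at least 2-fold, or 224 and 74 with a pseudocount of 0.1.

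**Figure D3:**
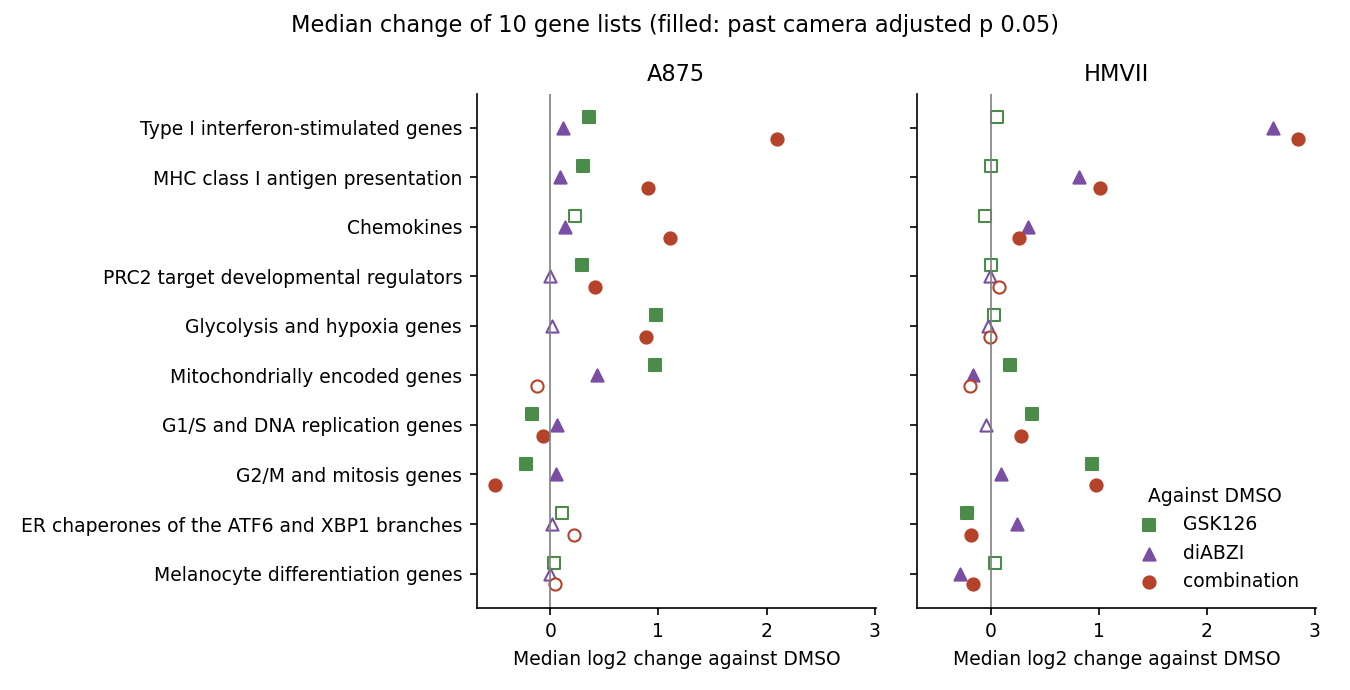
Median log2 change against DMSO of the tested members of 10 gene lists (horizontal axis) in A875 and HMVII for GSK126 (squares), diABZI (triangles) and the combination (circles), filled where camera passed at adjusted p 0.05. The interferon-stimulated genes stood at 0.36, 0.12 and 2.10 in A875 and at 0.06, 2.61 and 2.84 in HMVII.

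With both compounds HMVII showed the interferon response of diABZI together with the cell cycle changes of GSK126. OAS2 reached 96.8 ± 1.1 FPKM (6.52 ± 0.04), and IFIT3 (6.04 ± 0.04), IFIT1 (6.04 ± 0.05), IFI44 (5.58 ± 0.08), IFITM1 (5.56 ± 0.11), OASL (5.40 ± 0.04) and IFIT2 (5.25 ± 0.06) rose. HSPA6 (-2.40 ± 0.09), PRSS33 (-1.66 ± 0.05), UBL3 (-1.42 ± 0.02), ZMAT3 (-1.41 ± 0.03) and CERK (-1.28 ± 0.06) fell, as did the pseudogene CBX3P7 (-1.34 ± 0.06), which can share reads with other copies. Adjusted p was 3.7e-08 for CERK and lower for the others. Of 61 interferon-stimulated genes 59 rose and 1 fell (59 and 1 adjusted over the list alone, camera adjusted p = 3.25e-51), 48 of 48 G2/M genes rose (48 adjusted over the list alone, camera adjusted p = 1.24e-34), and 17 of 21 MHC class I genes rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 1.04e-06). ER chaperone genes fell in 21 of 32 and rose in 4 (21 and 4 adjusted over the list alone, camera adjusted p = 1.04e-06), and melanocyte genes fell in 22 of 38 and rose in 2 (23 and 2 adjusted over the list alone, camera adjusted p = 8.04e-05), with TYR, the tyrosinase gene, going from 254 ± 5.7 to 134 ± 0.5 FPKM. CCL5 averaged 38.6 ± 1.1 FPKM and CXCL10 3.42 ± 0.16 FPKM. In all 7254 genes passed, 3832 higher and 3422 lower, 226 and 49 of them by at least 2-fold, or 430 and 124 with a pseudocount of 0.1. Quantile normalization gave 3285 higher and 4114 lower.

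Against GSK126 alone in HMVII, the combination raised OAS2 by 6.25 ± 0.04, IFIT1 by 5.83 ± 0.05 and IFIT3 by 5.72 ± 0.04, and lowered ZMAT3 (-1.69 ± 0.03), CERK (-1.46 ± 0.06) and ODC1 (-1.40 ± 0.03), among 5363 genes, 2648 higher and 2715 lower, 149 and 34 of them by at least 2-fold (245 and 60 with a pseudocount of 0.1). Of the interferon-stimulated genes 60 of 61 rose (60 adjusted over the list alone, camera adjusted p = 1.54e-72). Against diABZI alone in HMVII, it raised KIF20A by 1.61 ± 0.04, CST1 by 1.60 ± 0.17 and CYP1A1 by 1.51 ± 0.08, and lowered HSPA6 (-3.15 ± 0.09), CALR (-1.16 ± 0.01) and APOD (-1.14 ± 0.06). The ER chaperone HSPA5 went from 912 ± 1.7 FPKM with diABZI to 484 ± 1.9 FPKM. All 48 G2/M genes rose (48 adjusted over the list alone, camera adjusted p = 4.94e-43). Interferon-stimulated genes rose further in 48 of 61 and fell in 3 (50 and 3 adjusted over the list alone, camera adjusted p = 1.27e-13), by a median of 0.32, with ISG15 up by 1.26 ± 0.09. This comparison called 5507 genes, 3345 higher and 2162 lower, 51 and 21 of them by at least 2-fold (177 and 51 with a pseudocount of 0.1), and quantile normalization gave 2710 higher and 2956 lower.

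In HMVII fewer genes departed from additivity than in A875. Of 61 interferon-stimulated genes 34 lay above the sum and 3 below (41 and 4 adjusted over the list alone, camera adjusted p = 7.31e-16), by a median of 0.23, with ISG15 at 0.93 ± 0.13, BST2 at 0.78 ± 0.04, CCL5 at 0.76 ± 0.07 and OAS2 at 0.69 ± 0.05. With a pseudocount of 0.1 the counts were 13 above and 3 below. On the FPKM scale itself 52 of 61 lay above the sum and 4 below it in both libraries, but there rises that add on the log2 scale also exceed the sum. OAS2 turned with the scale, at -0.26 with that pseudocount and -1.175 with voom. ER chaperone genes fell below the sum in 19 of 32 and above it in 0 (24 and 0 adjusted over the list alone, camera adjusted p = 7.24e-19), led by HSPA5 (-0.38 ± 0.01). IFNL2 exceeded the sum by 0.95 ± 0.14. Other departures named by the fixed rule were those of the pseudogene EIF4A1P12 (1.19 ± 0.31) and the divergent transcript CNNM3-DT (0.95 ± 0.16) above it, and of AGBL5-IT1 (-0.92 ± 0.21), CSNK2A3 (-0.80 ± 0.14) and GK-AS1 (-0.75 ± 0.17) below it, all of them overlapping or resembling other genes. In all 1520 genes departed from additivity, 874 above and 646 below, 12 and 6 of them by at least 2-fold, or 28 and 19 with a pseudocount of 0.1, 11 and 12 without HMVII DMSO replicate 2 and 16 and 11 without HMVII diABZI replicate 2. A separate fit of HMVII called 755 genes, and leaving out any single library gave between 951 and 1086.

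The lines were then compared directly. The change with GSK126 differed between HMVII and A875 for 9000 genes, that with diABZI for 4309 and that with the combination for 8930. With GSK126 the G2/M genes rose in HMVII and fell in A875, a median difference of 1.21, and the glycolysis and hypoxia genes differed by -1.002, while with diABZI the interferon-stimulated genes rose more in HMVII by a median of 2.42. IFIT1 rose more in HMVII with diABZI by 4.38 ± 0.08, while TMEM173 with GSK126 fell in HMVII and rose in A875, a difference of -0.68 ± 0.06. Without HMVII DMSO replicate 1 the fall of TMEM173 in HMVII was not past the threshold (-0.11). ISG15 rose less in HMVII than in A875 with diABZI (-1.11 ± 0.13) and with the combination (-2.61 ± 0.13). With DMSO it averaged 1.06 FPKM in HMVII and 11.3 in A875, so the pseudocount of 1 shrinks its rise more in HMVII. Part of these differences therefore comes from the scale. With GSK126 the difference was higher in HMVII for 3752 genes and lower for 5248, and after quantile normalization for 4548 and 3993, as the median over all genes went from -0.075 to 0.028. At least 2-fold differences numbered 237 higher and 677 lower with GSK126, 132 and 36 with diABZI, and 422 and 652 with the combination, or 432 and 1686, 211 and 102, and 681 and 1429 with a pseudocount of 0.1. After quantile normalization they were 307 and 437, 140 and 39, and 486 and 506, so the excess of lower differences with GSK126 and with the combination shrank.

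Genes raised by GSK126 in both lines numbered 1208, beside 1333.7 for independent lists (Fisher's exact test, one-sided, p = 1), and 620 were lowered in both, beside 643.2 (p = 0.88 in the same exact test). More genes passed in opposite directions, 1392 raised in A875 and lowered in HMVII and 1259 the reverse. With a pseudocount of 0.1 the genes lowered in both were 611 beside 569.6 (exact p = 0.0173), and those raised 1127 beside 1264.6. With no filter both shares turned to an excess, at 1023 raised beside 749.8 (exact p = 1.81e-30) and 514 lowered beside 298.4 (exact p = 2.09e-37). diABZI raised 207 genes in both lines beside 105.2 for independent lists (exact p = 4.63e-24) and lowered 192 beside 111.2 (exact p = 2.48e-16). The combination raised 1624 in both beside 1431.2 (exact p = 9.06e-14) and lowered 1081 beside 785.3 (exact p = 2.46e-40). Opposite calls numbered 190 (raised in A875, lowered in HMVII) and 139 (the reverse) with diABZI. With the combination they numbered 1305 and 1083. No number for independent lists was computed for opposite calls, so the overlaps alone do not show a shared response. At a minimum of 2-fold, diABZI raised 9 genes in both lines and the combination 87, beside 0.1 and 8.8 for independent lists.

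B2M (ENSG00000166710, chromosome 15, 44711487 to 44718877), without which MHC class I does not reach the cell surface, stood at 77.1 ± 0.37 FPKM in A875 with DMSO and rose to 256 ± 0.22 FPKM with the combination. It had 0 fragments in each of the 8 HMVII libraries, 217354340 fragments in all, where 3 fragments would be between 0.0164 and 0.0192 FPKM. The nearest protein-coding genes with at least 1 FPKM in A875 were low in HMVII too. PATL2, between SPG11 and B2M, was near 0 in both lines with DMSO (0.0261 FPKM in A875, 0 in HMVII) and is not informative. SPG11 averaged 0.199 ± 0.0031 FPKM in HMVII with DMSO, beside 4.71 ± 0.032 in A875, and TRIM69 had 2 fragments over the 8 HMVII libraries, beside 1.66 ± 0.011 FPKM in A875. Farther out, EIF3J (28.2 ± 1.3 FPKM in HMVII, 43.3 ± 0.12 in A875) and SORD (5.56 ± 0.067 and 3.55 ± 0.036) were expressed in both lines. These neighbours were looked at after the B2M values were seen.

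**Figure D4:**
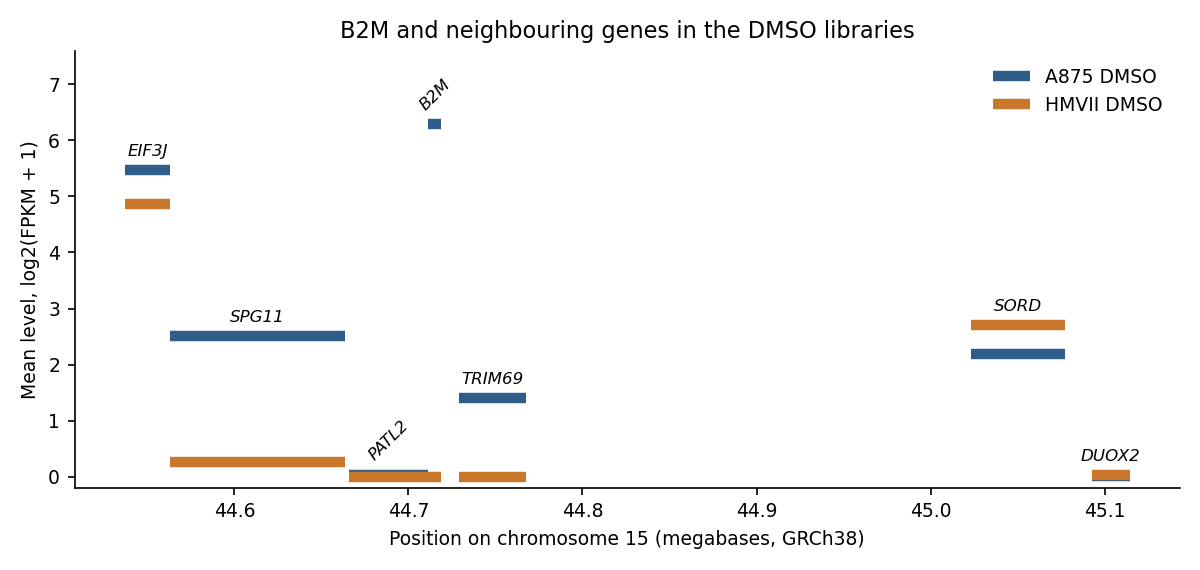
B2M and the 3 nearest protein-coding genes on each side, drawn at their positions on chromosome 15 (megabases) with their mean level in the DMSO libraries on the log2(FPKM + 1) scale, for A875 (blue) and HMVII (orange). SPG11, B2M and TRIM69 lie near 0 in HMVII, and EIF3J and SORD do not. PATL2 and DUOX2 lie near 0 in both lines.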

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

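The pseudocount of 0.1 and quantile normalization were alternatives fixed before the data were examined, and the other tests of explanations in this part were chosen after the results they measure were seen. The 3 patterns noticed in the data are weighed first, and they were not singled out by a test. The results after them were singled out because the change with a treatment differed between the 2 lines by a test of the difference itself, and each of those values is the log2 change in HMVII minus that in A875. The last result is a signal in data that the comparisons do not use. With 2 libraries per group no library was tested for lying far from the others. The difference between lines passed for 9000 genes with GSK126, 4309 with diABZI and 8930 with the combination. The lists given are those past camera at the preset correlation. The mitochondrially encoded genes follow the mitochondrial share of a library together, and what set that share was not tested. Over all comparisons, 156 of 217 such list calls stayed past the threshold with an estimated correlation, so some of the lists here may not.

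The first pattern is that the interferon-stimulated genes rose by more than the sum of the single-compound changes in A875, by a median of 1.488 on the log2 scale. The tables argue against the pseudocount as the whole cause, since the median was 1.653 with a pseudocount of 0.1, and against normalization, since it was 1.451 after quantile normalization. A higher STING level after GSK126 is a candidate explanation that stays open. TMEM173 rose with GSK126 by 0.499 in A875, and its change in HMVII, where the median departure was 0.230, differed by -0.679. However, with DMSO TMEM173 was similar in the lines, at 7.19 FPKM in A875 and 7.05 in HMVII. Even so, diABZI alone raised the interferon-stimulated genes more in HMVII, by a median of 2.424. HMVII is therefore a weak comparison for the departure, since its list already rose strongly with diABZI alone. The level of the STING protein and its activity were not measured.

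The second pattern is that B2M was listed at 0 in each of the 8 HMVII libraries. The authors' counting does assign reads to B2M, with at least 76.83 FPKM in each A875 library, which argues against a gap in the annotation. Loss of the chromosome segment that holds B2M may be the cause, since the expressed neighbours SPG11 and TRIM69 had HMVII to A875 ratios of 0.042 and 0 (median 0.021). However, SPG11 still had 490 fragments over the 8 HMVII libraries, and no DNA was sequenced. Silencing of B2M by EZH2 stays open: at most 0 B2M fragments were counted in an HMVII library with GSK126, but the PRC2 target regulators did not pass as a list in HMVII either (6 of 45 rose and 5 fell, camera adjusted p = 0.9), so this test does not settle it.

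The third pattern is that the 2 libraries of a group differed by little more than counting noise. The median squared difference over the counting variance was at least 1.467 in the 8 pairs, and a library deposited again under the other number would give 0. Repeat libraries from one culture or one RNA may explain the tightness, since the median ratio among the genes with the most fragments was 1.082 times that among the genes with the fewest, whereas variation between cultures would grow with the count. The labels do not say whether the 2 libraries of a group came from separate cultures, and no biological explanation was tested. If they came from the same culture, the calls cannot separate the effect of a compound from a difference between cultures.

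With GSK126 the median difference of a list between the lines was -0.285 for the interferon-stimulated genes, -0.351 for MHC class I, -0.411 for ER chaperones, 0.423 for anti-apoptotic genes, 0.497 for G1/S genes, 1.206 for G2/M genes and 0.468 for invasive AXL-type genes. It was -1.002 for glycolysis and hypoxia genes, 0.174 for oxidative phosphorylation, -0.831 for mitochondrially encoded genes, -0.352 for ribosomal proteins, -0.185 for autophagy and lysosome genes, -0.315 for immediate early genes and -0.320 for senescence-associated secreted factors.

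With diABZI it was 0.074 for cGAS-STING components, 2.424 for interferon-stimulated genes, 0.141 for interferons and their receptors, 0.064 for NF-kB targets, 0.243 for chemokines, 0.766 for MHC class I, 0.202 for ER chaperones, 0.127 for pro-apoptotic genes, 0.204 for anti-apoptotic genes and 0.109 for p53 targets. It was -0.121 for G1/S genes, 0.059 for G2/M genes, -0.240 for melanocyte genes, 0.168 for invasive AXL-type genes, -0.205 for cholesterol synthesis, -0.153 for oxidative phosphorylation, -0.628 for mitochondrially encoded genes, -0.075 for ribosomal proteins, 0.075 for heat shock and oxidative stress genes and 0.095 for TGF-beta and matrix genes.

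With the combination it was -0.407 for PRC2 target regulators, 0.667 for interferon-stimulated genes, -0.396 for MHC class II, -0.354 for ER chaperones, 0.597 for anti-apoptotic genes, 0.385 for G1/S genes, 1.487 for G2/M genes and -0.366 for melanocyte genes. It was 0.470 for invasive AXL-type genes, -0.917 for glycolysis and hypoxia genes, -0.286 for ribosomal proteins, -0.243 for autophagy and lysosome genes and -0.634 for senescence-associated secreted factors.

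Among the fixed genes, the change with GSK126 differed for ISG15 (-0.488), MITF (0.439), EZH2 (0.397), IFIT1 (-1.015), TMEM173 (-0.679), IRF3 (-0.504), HSPA5 (-0.641), ATF4 (0.230), EED (0.360), CXCL10 (-0.628), SUZ12 (0.190), CCL5 (-0.284) and CD274 (1.163). With diABZI it differed for ISG15 (-1.109), EZH2 (-0.197), IFIT1 (4.377), TMEM173 (0.318), HSPA5 (0.495), CXCL10 (1.252), SUZ12 (-0.140), CCL5 (1.215) and CD274 (0.643). With the combination it differed for ISG15 (-2.612), MITF (0.372), EZH2 (0.378), IFIT1 (0.462), TMEM173 (-0.815), IRF3 (-0.333), HSPA5 (-1.019), CXCL10 (-0.470) and CD274 (1.221). ISG15 was low in HMVII with DMSO (1.06 FPKM), where the pseudocount of 1 shrinks its rise.

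MT-TY, a mitochondrial tRNA gene outside the tested genes, was listed at 62.3 FPKM (108 fragments over 66 bases) in HMVII combination replicate 1. It was at 0 in the other 7 libraries numbered 1 and had no value in those numbered 2.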

How the results depend on the processing

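Voom on the recovered counts was the only alternative chosen after the data were seen. Of 302 named values past the threshold, 246 stayed past it in the same direction under each alternative that tested them, 55 were lost under at least 1 and 3 turned under at least 1. The losses numbered 19 with a pseudocount of 0.1, 19 with no filter, 13 with quantile normalization, 7 with the replicate block, 25 with voom, 21 of 268 with a separate fit per line and 39 on leaving out a library. CCL5 turned with quantile normalization (A875, GSK126, from 0.231 to -0.041), as did ATF4 (A875, combination against GSK126, from 0.070 to -0.043). OAS2 in the departure from additivity in HMVII went from 0.692 to -0.259 with a pseudocount of 0.1 and to -1.175 with voom. Its DMSO level is low, so the pseudocount sets much of its single-compound changes.

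A 2-fold minimum left 572, 19 and 749 genes in A875 for GSK126, diABZI and the combination against DMSO, and 136 and 709 for the combination against GSK126 and diABZI. The same minimum left 81, 172, 275, 183 and 72 in HMVII, 165 and 18 departing from additivity in A875 and HMVII, and 914, 168 and 1074 differing between the lines. By construction it keeps only large changes, and its counts rest on the pseudocount of 1, which shrinks the changes of genes with low levels. With a pseudocount of 0.1 at least 2-fold were 1450 up and 212 down for GSK126, 31 and 16 for diABZI and 1451 and 313 for the combination in A875, and 150 and 76, 224 and 74, and 430 and 124 in HMVII. With voom they were 1757 and 238, 33 and 10, and 1701 and 341 in A875, and 215 and 117, 269 and 99, and 556 and 167 in HMVII. The excess of 2-fold rises over falls for the combination against GSK126 in A875 (100 and 36) went with the scale, to 156 and 154 with that pseudocount and 186 and 223 with voom, and so did that of departures above the sum in A875 (101 and 64), to 151 and 191 and to 157 and 209. After quantile normalization both excesses stayed, at 98 and 23 and at 103 and 47. For the combination against diABZI in A875 the counts were 1427 and 267, and 1663 and 294, and in HMVII against GSK126 245 and 60, and 306 and 71, and against diABZI 177 and 51, and 243 and 70. For departures from additivity in HMVII (12 and 6) they were 28 and 19, and 30 and 12, with 13 and 13 under the replicate block, 10 and 10 with no filter and 11 and 12 without HMVII DMSO replicate 2. Between the lines voom gave 437 and 1889, 204 and 107, and 702 and 1576.

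The count for diABZI in A875 rose from 1217 to 1867 with voom, and leaving out single libraries gave between 581 and 610. For departures from additivity in HMVII a separate fit gave 755 beside 1520, and leaving out single libraries gave between 951 and 1086. A lone library is then assumed to vary like the other groups, and fewer libraries give less power. The cause of the rise with voom was not tested. With the replicate number as a block, diABZI in A875 called 1129 genes and GSK126 in A875 9256. Same-numbered libraries deviated together only weakly. Among genes with a mean of at least 200 fragments the correlations lay between -0.005 and 0.058, most of them slightly above 0.

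Genes raised by diABZI in both lines went from 207 to 132 with no filter and to 129 with quantile normalization, and those lowered by the combination from 1081 to 1635 with quantile normalization, and the cause was not tested. For GSK126, genes raised in both lines were fewer than independent lists would share (1208 beside 1333.7), and with no filter more (1023 beside 749.8). Genes lowered in both were fewer too (620 beside 643.2), but more with a pseudocount of 0.1 (611 beside 569.6, Fisher's exact p = 0.0173) and with no filter (514 beside 298.4, Fisher's exact p = 2.09e-37). Without the filter the expected numbers fall, because 34562 genes then form the background. Fry, which tests each list against no change, called 445 of 510 list tests, beside 217 by camera and 156 by camera with an estimated correlation. No list past the threshold changed direction in the alternatives run. The libraries held 25663007 to 30098308 fragments, so 3 fragments, the floor of a count of 0, are between 0.0164 and 0.0192 FPKM for B2M in HMVII.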

Other observations

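In HMVII the 2 compounds moved the ER chaperones in opposite directions. HSPA5, the chaperone BiP, went from 681 ± 5.9 FPKM with DMSO to 912 ± 1.7 with diABZI and to 470 ± 4.8 with GSK126, and with both compounds it lay at 484 ± 1.9, near GSK126 alone. In A875 it rose with GSK126 (log2 change of 0.11) and with the combination (0.53) and fell slightly with diABZI (-0.07, and not past the threshold after quantile normalization, at -0.022).

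Among markers of other cell types, 3 of 5 tested fibroblast genes rose and 1 fell in A875 with GSK126 (camera adjusted p = 0.538), and 2 of 5 tested endothelial genes rose and 3 fell (camera adjusted p = 0.486). No hypothesis of this part was tested.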
